A study of Homo sapiens with 6 samples.

How the data were processed

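RNA from MDA-MB-231 cells treated for 72 h with DMSO or 2 µM Azeliragon was extracted with a column kit and polyadenylated RNA was sequenced, per the labels' protocols. The series holds 6 libraries, 3 per condition. The authors deposited a table of raw counts per gene, with a column per library. STAR 2.6.1d, featureCounts 1.5.0-p3, limma and the genome build GRCh38 are named, per the submitters' processing notes, without the role of each. The strand setting, the treatment of reads that match several places and the gene annotation are not given in the sources used here. Genes that overlap on opposite strands, and close relatives or pseudogenes, can therefore share reads, and their counts are treated as uncertain.

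Of 58735 names in the deposited count table, 58722 were gene names of GENCODE release 29, which was used for coordinates, gene types, length and GC content. A total of 1741 entries shared their name with another, and SOD2 was read from the entry with the higher total. A further 2 entries whose names had been turned into dates held 0% of the counts and were left out. Library totals were 44191944, 43091452 and 44313584 counts for DMSO a, b and c, and 42851949, 43772671 and 41455979 for Azeliragon a, b and c. A single read corresponded to 0.0222 to 0.0241 CPM, and the limit of 3 counts to 0.0665 to 0.0723 CPM. Intervals from reads cover counting error only, since reads without molecular identifiers are not independent molecules.

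Genes were kept with filterByExpr of edgeR 4.0.16, libraries were scaled by TMM, and the conditions were compared with glmQLFit and glmQLFTest with treatment as the only term. An adjusted p under 0.05 (Benjamini-Hochberg over 16081 genes) was the threshold. Levels are TMM-scaled CPM, the usual unit of counts relative to the library total, with the SD over 3 libraries, and fold changes are those of the edgeR fit, with standard errors on the log2 scale. Gene lists were compared with all other genes by camera of limma 3.58.1 with an inter-gene correlation of 0.01, adjusted over the 30 of 31 lists that had at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. R 4.3.3, Python 3.11.15, bedtools 2.31.1 and matplotlib 3.10.9 were used.

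The grouping, the tests, the 31 gene lists, the other settings listed at the end of this account and the rule for naming genes were chosen before the data were examined. The rule named AGER and SNAI1. It added the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between conditions, leaving out clone names and pseudogenes. From each of the 6 lists closest to the title of the series it took called members and up to 4 abundant members that were not called. From each other list it took up to 4 called members, or the member with the smallest p. It gave 142 genes, of which the text names a part. Some of these genes are not reported here. CDH1, TWIST1 and TWIST2, which could not be tested, COL5A2 and the gene families of the closing section were named after their values were seen.

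Within each condition every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 4.62, so no library was counted as a copy of another. On counts simulated from the real means and library sizes with 200 changed genes, among 15813 genes in the test, edgeR called 36% of 50 genes changed 1.3-fold, 46% of those changed 1.5-fold, 70% of those changed 2-fold and 94% of those changed 4-fold. It also called 7 unchanged genes among 130 calls. The simulation gave a gene the same spread in both conditions and held no trend on length. In the data the biological CV, the spread between libraries beyond counting noise, was 12.5% in DMSO and 5.64% with Azeliragon. The simulated shares may therefore not carry over to these libraries.

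The other settings tried were RLE size factors, library totals, no filter on low counts, a stricter filter (1 CPM in 3 libraries and a mean count of 50), DESeq2 1.42.0, limma-voom, the replicate letter as a block, each library left out in turn, and a test against a 1.5-fold change with glmTreat. Removal of each library's trend on GC content and transcript length, alone and without DMSO a, was added after seeing the data.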

Results

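Gene expression was measured by RNA sequencing of polyadenylated RNA in MDA-MB-231 cells, a human triple-negative breast cancer line with mesenchymal features that is widely used as a model of metastasis. Cells were kept for 72 h in the vehicle DMSO or in 2 µM Azeliragon, a small-molecule inhibitor of RAGE, the receptor for advanced glycation end products encoded by AGER. Each condition had 3 libraries, lettered a, b and c, and the deposited counts summed to between 41455979 and 44313584 per library. The labels do not say whether the libraries of a condition came from separate cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Camera p-values compare the genes of a list with all other genes. With a preset correlation their size is no measure of the spread between libraries. The title of the series concerns RAGE and SNAIL signalling in epithelial-mesenchymal plasticity, and the comparison asks which transcripts differ when the receptor is inhibited.

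SNAI1, which encodes the transcription factor SNAIL, was 4.35-fold lower with Azeliragon (log2 fold change -2.12, SE 0.33; adjusted p = 0.00236, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The gene lies on chromosome 20 at 49982999 to 49988886 on the plus strand (GRCh38, GENCODE 29) and is weakly expressed in these cells. Its level was 1.88 ± 0.25 CPM (TMM-scaled counts relative to the library total) in DMSO and 0.43 ± 0.19 with Azeliragon (SD, n = 3 each). These levels rest on 73, 91 and 82 reads in the DMSO libraries and 28, 14 and 13 in the Azeliragon libraries. Azeliragon libraries held 18.3% of all SNAI1 reads, with an exact 95% binomial interval of 14.1% to 23.1%, where 49.3% would be held without a change. With each library left out in turn the log2 fold change lay between -2.55 and -1.95. AGER, on chromosome 6 at 32180968 to 32184324 on the minus strand, did not pass the threshold. AGER stood at 6.74 ± 0.69 CPM in DMSO and 6.15 ± 0.16 with Azeliragon (SD, n = 3 each; log2 fold change -0.13, 95% interval -0.40 to 0.13; edgeR adjusted p = 0.594). Azeliragon acts on the receptor protein, so AGER RNA is no check of the treatment.

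**Figure D1:**
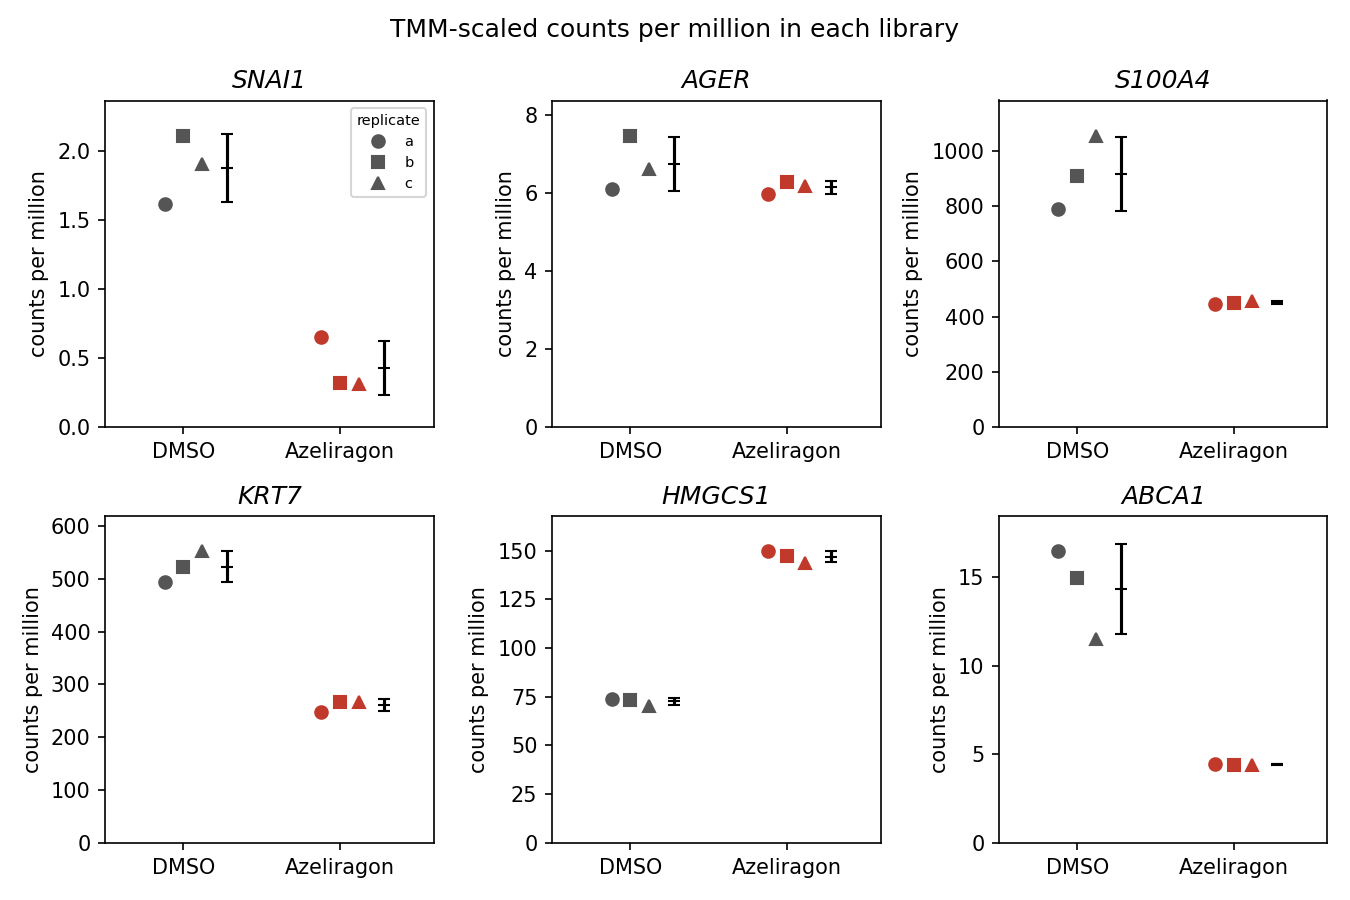
TMM-scaled CPM of 6 genes (vertical axes, linear and starting at 0) in the 3 DMSO and 3 Azeliragon libraries; each symbol is a library and the bar beside each group is the mean with its SD. SNAI1, S100A4, KRT7 and ABCA1 lie lower in all 3 Azeliragon libraries than in any DMSO library, HMGCS1 lies higher in all 3, and AGER overlaps between the groups.

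Across the transcriptome, 1009 of 16081 genes tested passed the threshold, of which 442 rose and 567 fell with Azeliragon. Most changes were small. The median size was 1.37-fold among genes that rose and 1.48-fold among those that fell, and 33 rose and 101 fell by 2-fold or more. IL24, a secreted cytokine, rose 4.28-fold, from 5.48 ± 0.40 to 23.5 ± 2.0 CPM (SD, n = 3 each; edgeR adjusted p = 2.87e-06). FGF5, a fibroblast growth factor, rose 2.37-fold and HDAC9, a histone deacetylase, rose 2.04-fold. The other large rises with a mean level of at least 5 CPM were those of CYP51A1, C6orf223, LINC00702, INSYN2B and HMGCS1. ABCA1, a cholesterol exporter on chromosome 9 at 104781002 to 104928237, fell 3.23-fold, from 14.3 ± 2.5 to 4.43 ± 0.035 CPM (SD, n = 3 each; edgeR adjusted p = 3.41e-05). LAPTM5 fell 3.14-fold, ANGPTL4 2.98-fold, LFNG, which modifies Notch receptors, 2.83-fold, and the granin SCG2 2.72-fold. HLA-DPB1, SLC43A2 and the anchoring fibril collagen COL7A1 completed the 8 largest falls at a mean level of at least 5 CPM. HLA-DPB1 can share reads with related genes and, like CYP51A1, C6orf223, HMGCS1 and ANGPTL4, overlaps a gene on the opposite strand, so these counts are uncertain.

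The number of genes called depended on single libraries, although the direction of no called gene did. Library DMSO a stood apart from the other DMSO libraries, at -0.23 on the first principal component (37.6% of the variance) where DMSO b and c lay at 30.1 and 33.7 and the Azeliragon libraries between -23.0 and -19.0. Without DMSO a 3916 genes passed, 45.4% of them lower with Azeliragon where 56.2% of the 1009 were, and they included 1007 of the 1009. The 2909 others changed by a median 1.24-fold and split by transcript length, with a median of 2200 bases for those lower and 5482 for those higher. Across genes the correlation of log2 fold change with log2 length was 0.327 without DMSO a and 0.197 with all 6 libraries. The count was 473 without DMSO b, 445 without Azeliragon a, 500 without Azeliragon b and 448 without Azeliragon c. Groups did not overlap for any of the 1009 genes, and they did not overlap for 25.3% of all genes tested, where chance gives 10%.

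The lists of epithelial and mesenchymal markers each held more falls than rises, although most members did not pass. Of 31 epithelial markers tested, 1 rose, 9 fell and 21 did not pass (3 rose and 9 fell adjusted over the list alone). KRT7, a keratin of simple epithelia on chromosome 12 at 52232520 to 52252186, fell 2.00-fold from 523 ± 30 to 261 ± 11 CPM (SD, n = 3 each; edgeR adjusted p = 7.77e-06), although an antisense gene overlaps it. KRT80, MUC1 and SPINT1 also fell, by 1.75-fold, 2.69-fold and 2.52-fold, whereas the desmosomal gene DSP rose 1.53-fold. SPINT1 overlaps a gene on the opposite strand and MUC1 a gene on the same strand, so their counts are uncertain. The call of DSP was lost without DMSO b or Azeliragon c (edgeR adjusted p up to 0.0587). KRT8, KRT18 and KRT19 did not pass, with log2 fold changes of -0.12, -0.21 and -0.17. CDH1, the epithelial cadherin, had 0 reads in DMSO and 1 with Azeliragon. Its RNA was near absent at this depth in both conditions, so a change could not be tested. The list ranked below other genes by camera with a preset correlation (adjusted p = 2.01e-05), but not with an estimated one (adjusted p = 0.0749 with an estimated correlation). The estimate for this list, 0.0102, was near the preset 0.01, so a higher correlation does not account for the loss of the call. Without DMSO a 18 epithelial markers passed, and without any other single library 8 to 10 passed.

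Of 34 mesenchymal markers tested, 2 rose, 11 fell and 21 did not pass (3 rose and 12 fell adjusted over the list alone). Among the collagen genes of the list, COL5A1 fell 1.90-fold, COL6A1 1.82-fold, COL6A3 2.13-fold and COL1A2 3.88-fold, whereas COL5A2, named after its values were seen, was higher without passing (log2 fold change 0.71; edgeR adjusted p = 0.0756). TGFBI, an extracellular matrix protein induced by TGF-beta, fell 2.12-fold from 229 ± 1.5 to 108 ± 7.3 CPM (SD, n = 3 each; edgeR adjusted p = 4.22e-06). AXL rose 1.20-fold, a call that was lost without any single library other than DMSO a (edgeR adjusted p up to 0.164). Among the most abundant members, VIM (-0.15), FN1 (-0.06), CD44 (0.05) and ITGB1 (0.04) had log2 fold changes that did not pass. The list ranked low by camera (adjusted p = 7.76e-06), and this call was lost at adjusted p = 0.124 with an estimated correlation. Without DMSO a 21 mesenchymal markers passed, without DMSO c 12, and without DMSO b or any single Azeliragon library 9. Of 6 fibroblast markers 4 fell and none rose (4 fell adjusted over the list alone; camera adjusted p = 4.92e-06; adjusted p = 0.0749 with an estimated correlation). These 4, COL1A1, COL1A2, COL6A3 and PDGFRB, are also in the mesenchymal list, so they add no separate evidence, and the 2 members outside that list did not pass. Of 9 luminal breast epithelium markers 2 fell and none rose (2 fell adjusted over the list alone; camera adjusted p = 0.00877; adjusted p = 0.267 with an estimated correlation). The luminal call was lost without DMSO b (0.0744) or DMSO c (0.107), and 5 luminal markers passed without DMSO a, 1 without DMSO b or Azeliragon b and 0 without Azeliragon a or Azeliragon c.

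Among 14 transcription factors of the epithelial-mesenchymal transition, SNAI1, SOX4 and FOXQ1 fell, FOXC1 rose and 10 did not pass (2 rose and 4 fell adjusted over the list alone). SOX4 fell 2.37-fold (edgeR adjusted p = 0.000587), although it overlaps a gene on the opposite strand. FOXQ1 fell 1.53-fold and FOXC1 rose 1.55-fold. The call of FOXQ1 was lost without DMSO b, Azeliragon a or Azeliragon c (edgeR adjusted p up to 0.104), and that of FOXC1 without DMSO b (0.0522). The abundant FOSL1 and SOX9 did not pass, with log2 fold changes of 0.10 and 0.19. TWIST1 and TWIST2 had 0 reads in all 6 libraries. The list median was 0.06, while its mean (-0.14) and its camera direction were negative (adjusted p = 0.478; adjusted p = 0.682 with an estimated correlation). The list had 8 members past the threshold without DMSO a and 2 without DMSO b. With each library's trend on GC content and transcript length removed, a setting added after seeing the data, 3 members rose and 4 fell.

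Of 18 genes for RAGE, its ligands and its adaptors, 5 fell, none rose and 13 did not pass (7 fell adjusted over the list alone). All 5 were genes of the S100 family, and membership of the list does not show that each product binds RAGE. In the S100 family, chosen after its values were seen, 7 of 12 genes fell and none rose. Among them were S100A3 and S100A5, which are outside the list. S100A4, on chromosome 1 at 153543613 to 153550136, fell 2.03-fold from 918 ± 133 to 451 ± 5.6 CPM (SD, n = 3 each; edgeR adjusted p = 4.38e-05), and S100A2 fell 2.16-fold (adjusted p = 0.000165 in the same test). S100A6, S100A10 and S100A16 fell by 1.43-fold, 1.28-fold and 1.27-fold, and each of these 3 calls was lost without any single Azeliragon library. Those of S100A10 and S100A16 were also lost without DMSO b, and that of S100A10 without DMSO c (edgeR adjusted p up to 0.0532, 0.173 and 0.0989 for the 3 genes). HMGB1, a RAGE ligand, had a log2 fold change of -0.18 and did not pass. The list ranked low by camera (adjusted p = 4.86e-05; adjusted p = 0.180 with an estimated correlation). It had 11 members past the threshold without DMSO a, 3 without DMSO b and 2 without any single Azeliragon library.

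Of 28 NF-kB targets, 8 fell, none rose and 20 did not pass (4 rose and 11 fell adjusted over the list alone). BCL3 fell 1.75-fold, the growth factor CSF2 1.65-fold and PLAU, the urokinase plasminogen activator, 1.54-fold from 1555 ± 119 to 1008 ± 33 CPM (SD, n = 3 each; edgeR adjusted p = 0.000183). With the GC and length trend removed 2 of these targets rose and 10 fell. The list ranked low by camera (adjusted p = 4.94e-05; adjusted p = 0.150 with an estimated correlation). It had 16 members past the threshold without DMSO a and 5 without DMSO b or Azeliragon c. Of 15 genes associated with lung metastasis, 4 fell, 1 rose and 10 did not pass (8 fell and 1 rose adjusted over the list alone). ANGPTL4, ID1, ID3 and CXCL1 fell, and the collagenase MMP1 rose 5.21-fold from 1.35 ± 0.15 to 7.06 ± 0.91 CPM (SD, n = 3 each; edgeR adjusted p = 1.14e-05). The MMP1 count is uncertain because a pseudogene overlaps it on the opposite strand. The call of ID3 was lost without DMSO b, Azeliragon a or Azeliragon c (edgeR adjusted p up to 0.0645). With the GC and length trend removed 8 of these genes fell and 1 rose. The lung metastasis list ranked low by camera (adjusted p = 0.00108; adjusted p = 0.109 with an estimated correlation).

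The clearest group change was in cholesterol synthesis and uptake. Of 25 genes tested, 22 rose, none fell and 3 did not pass (23 rose adjusted over the list alone). Without DMSO a 24 members passed, without DMSO c 21, and without any other single library 17 to 19. HMGCS1, which makes the precursor of mevalonate and lies on chromosome 5 at 43289395 to 43313512, rose 2.02-fold from 72.6 ± 1.9 to 147 ± 3.1 CPM (SD, n = 3 each; edgeR adjusted p = 4.22e-06). ACAT2 and DHCR7 each rose 1.67-fold, although ACAT2 overlaps genes on the opposite strand. The list ranked high by camera (adjusted p = 1.08e-55) and was the 1 list of the 30 tested that passed with an estimated correlation (adjusted p = 0.00196 with an estimated correlation). In contrast, 2 of 8 genes of cholesterol export and LXR targets fell, ABCA1 and NR1H3, which encodes LXR-alpha, and none rose (4 fell adjusted over the list alone; camera adjusted p = 3.79e-05; adjusted p = 0.0749 with an estimated correlation). The NR1H3 call was lost without DMSO b, Azeliragon a or Azeliragon c (edgeR adjusted p up to 0.106). In fatty acid synthesis and desaturation 3 of 19 genes rose and 1 fell (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0190; adjusted p = 0.586 with an estimated correlation). The gene that fell, SREBF1, fell 1.49-fold and ACSS2 rose 1.41-fold. DESeq2 called 8 members of this list and limma-voom 5, where edgeR called 4. Without DMSO a 13 of these genes passed, and 2 passed without DMSO b, Azeliragon a or Azeliragon c. The camera call of that list was lost without DMSO b (adjusted p = 0.0744) or DMSO c (0.0669). It was also lost (0.0770) when the GC and length trend was removed. There the list median was 0.08 in place of 0.13, the median SE was 0.06 in place of 0.08, and 7 members rose in place of 3. What ended the call was not tested.

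**Figure D2:**
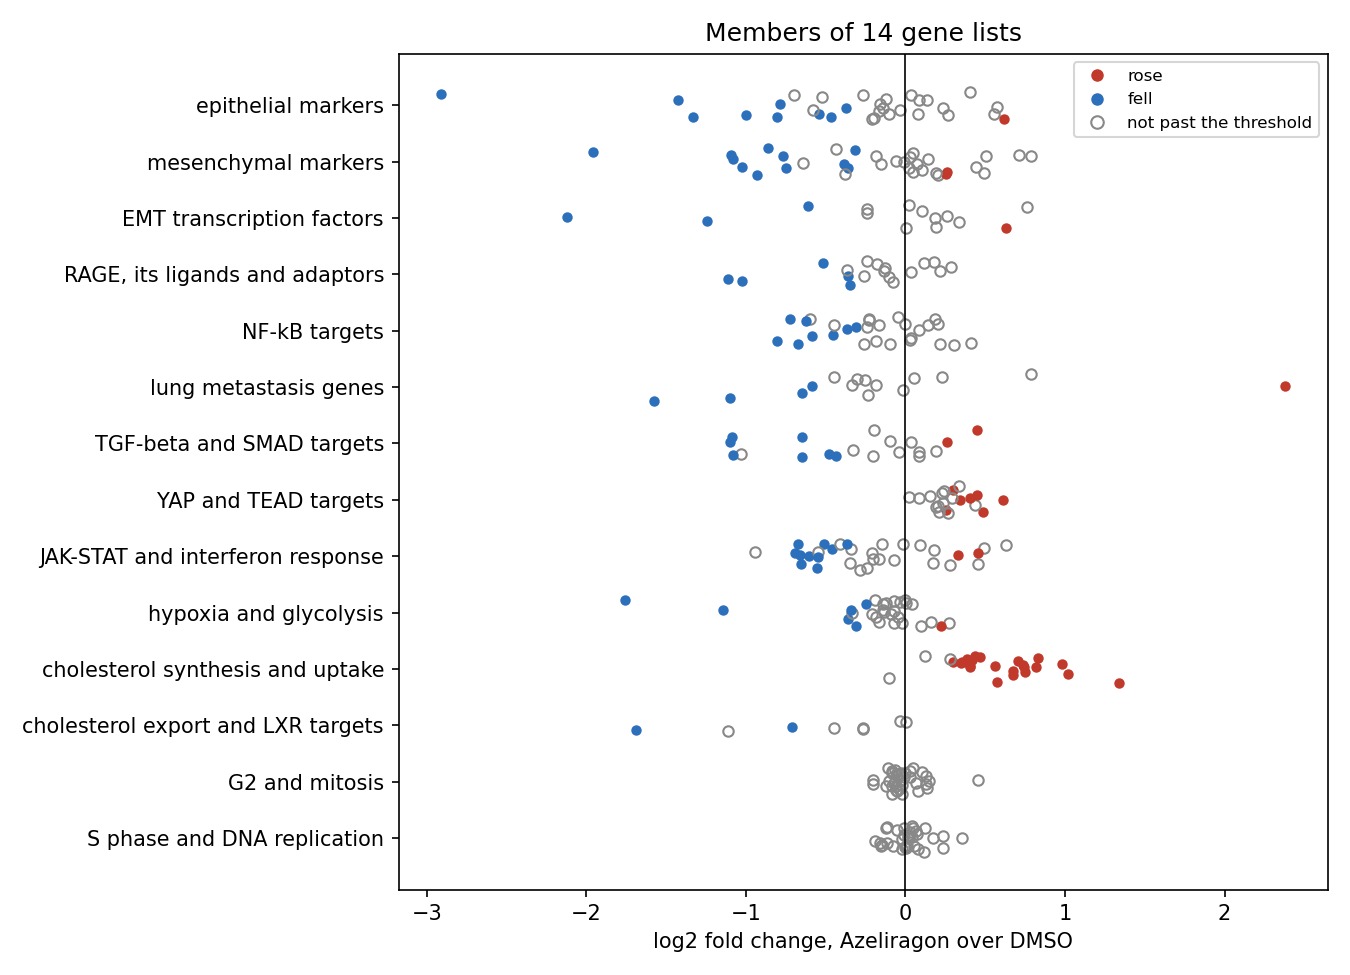
Log2 fold change of Azeliragon over DMSO (horizontal axis) for each tested member of 14 gene lists (vertical axis); filled points passed the edgeR threshold and rose (red) or fell (blue), and open points did not pass. In cholesterol synthesis and uptake 22 of 25 genes rose, while 9 of 31 epithelial and 11 of 34 mesenchymal markers fell and none of the 34 genes of S phase or 34 of G2 and mitosis passed.

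Targets of several signalling pathways also moved. Called genes can be in several lists, so the lists are not fully separate evidence. S100A4 is in the mesenchymal and RAGE lists, CXCL1 in the NF-kB and lung metastasis lists, and TGFBI in the mesenchymal and TGF-beta lists. ID1 and ID3 are in the lung metastasis and TGF-beta lists. Of 19 TGF-beta and SMAD targets, 7 fell, among them PMEPA1 (2.13-fold), ID1 (2.15-fold) and TGFB1 (1.35-fold), and 2 rose (10 fell and 3 rose adjusted over the list alone; camera adjusted p = 3.48e-09; adjusted p = 0.0749 with an estimated correlation). This list had 5 members past the threshold without DMSO b or any single Azeliragon library. Of 20 YAP and TEAD targets, 7 rose, among them ANKRD1 (1.53-fold) and WWC1 (1.32-fold), and none fell (14 rose adjusted over the list alone; camera adjusted p = 2.01e-10; adjusted p = 0.150 with an estimated correlation). With the GC and length trend removed 13 of these targets rose and none fell. The YAP and TEAD list had 19 members past the threshold without DMSO a, 3 without DMSO b or Azeliragon b, 4 without Azeliragon a and 2 without Azeliragon c. Of 32 JAK-STAT and interferon response genes, 10 fell, among them HLA-B (1.59-fold), GBP1 (1.61-fold) and IFITM3 (1.52-fold), and 2 rose (14 fell and 4 rose adjusted over the list alone; camera adjusted p = 5.81e-05; adjusted p = 0.0749 with an estimated correlation). HLA-B and IFITM3 can share reads with close relatives. This list had 6 members past the threshold without Azeliragon a or Azeliragon c. Of 29 hypoxia and glycolysis genes, 6 fell, among them CA9, a carbonic anhydrase induced by hypoxia (3.39-fold), and 1 rose (8 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00108; adjusted p = 0.162 with an estimated correlation). With the GC and length trend removed 9 hypoxia and glycolysis genes fell and 2 rose. This hypoxia list had 14 members past the threshold without DMSO a, 3 without Azeliragon a, 2 without Azeliragon b and 1 without DMSO b or Azeliragon c. Of 20 unfolded protein response genes 6 fell and none rose (8 fell adjusted over the list alone; camera adjusted p = 0.00294; adjusted p = 0.182 with an estimated correlation), and none of the 6 kept its call in every set of 5 libraries. That list had 12 members past the threshold without DMSO a, 1 without DMSO b, Azeliragon a or Azeliragon b and 0 without Azeliragon c.

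Other lists did not rank apart from the remaining genes by camera with all 6 libraries. With the GC and length trend removed, the adhesion list (camera adjusted p = 0.00697) and the aryl hydrocarbon list (0.0381) passed, lower (adjusted p = 0.586 and 0.204 with an estimated correlation and no trend removed), with medians that went from -0.05 and -0.04 to -0.11 in both and median SEs from 0.08 and 0.14 to 0.06 and 0.13. Of 27 MAPK and AP-1 response genes 2 rose, DUSP5 by 1.88-fold, and 4 fell, including JUNB and EGR1 (3 and 9 adjusted over the list alone; camera adjusted p = 0.0617). Matrix proteases and inhibitors moved both ways, with 3 rises and 6 falls among 19 (4 and 6 adjusted over the list alone; camera adjusted p = 0.662). The median and mean of that list, 0.04 and 0.07, were positive and its camera direction was negative. Integrins and other adhesion genes had 1 rise and 4 falls among 32, with ITGB4 falling 1.57-fold (2 and 6 adjusted over the list alone; camera adjusted p = 0.107). Lysosome and autophagy genes had 4 rises, including NPC1 (1.72-fold) and SQSTM1 (1.51-fold), and 4 falls, including the protease CTSD (2.27-fold), among 32 (7 and 6 adjusted over the list alone; camera adjusted p = 0.341). ATF4 and amino acid response genes had 2 rises, including PPP1R15A (1.70-fold), and 2 falls among 23 (2 and 4 adjusted over the list alone; camera adjusted p = 0.662). NRF2 and oxidative stress genes had 1 rise and 3 falls among 22, AKR1C3 falling 1.85-fold (1 and 5 adjusted over the list alone; camera adjusted p = 0.0617). Aryl hydrocarbon and xenobiotic response genes had 2 falls among 10 (3 adjusted over the list alone; camera adjusted p = 0.0617). Cell cycle inhibitors and apoptosis genes had 1 rise and 1 fall among 20 (2 and 1 adjusted over the list alone; camera adjusted p = 0.480).

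Removal of the GC and length trend took the rises and falls to 3 and 6 among MAPK genes, 5 and 7 among protease genes, 3 and 6 among adhesion genes, 6 and 6 among lysosome genes, 4 and 4 among ATF4 genes, 2 and 5 among NRF2 genes, 0 and 3 among aryl hydrocarbon genes and 2 and 1 among cell cycle inhibitor or apoptosis genes. Single libraries moved the counts too. Without DMSO a, 13 MAPK genes, 14 adhesion genes, 16 lysosome genes, 8 ATF4 genes, 12 NRF2 genes and 7 cell cycle inhibitor or apoptosis genes passed. Without DMSO b, 5 protease genes, 3 adhesion genes, 4 lysosome genes, 2 NRF2 genes, 1 aryl hydrocarbon gene and 1 cell cycle inhibitor or apoptosis gene passed. Without a single Azeliragon library, 4 or 5 protease genes, 2 adhesion genes, 3 or 4 lysosome genes, 2 NRF2 genes, 1 aryl hydrocarbon gene and 0 to 2 cell cycle inhibitor or apoptosis genes passed, the lowest of the last without Azeliragon c. By camera the MAPK list passed without DMSO c (adjusted p = 0.0304) or Azeliragon c (0.0214), and the adhesion list without DMSO c (0.0164) or Azeliragon c (0.0489). The NRF2 list passed without DMSO a (0.0150), Azeliragon b (0.0483) or Azeliragon c (0.0489), and the aryl hydrocarbon list without DMSO c (0.0261) or Azeliragon c (0.0489). These calls use the preset correlation, and with an estimated correlation and all 6 libraries the adjusted p was 0.351 for the MAPK, 0.586 for the adhesion, 0.559 for the NRF2 and 0.204 for the aryl hydrocarbon list.

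None of the 34 genes of S phase and DNA replication passed in edgeR, DESeq2 or limma-voom, and 7 had an unadjusted p under 0.05 (camera adjusted p = 0.772). None of the 34 genes of G2 and mitosis passed in edgeR or limma-voom, 1 passed in DESeq2, and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.662). None of 16 heat shock genes passed in any of these tools, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.749). The median of the heat shock list was -0.02, and its mean (0.02) and camera direction were positive. None of the 13 mitochondrially encoded mRNAs passed in these tools either, and 6 had an unadjusted p under 0.05 (camera adjusted p = 0.268). Without DMSO a, 8 genes of S phase, 8 of G2 and mitosis, 3 heat shock genes and 11 mitochondrial mRNAs passed. With the GC and length trend removed 4 mitochondrial mRNAs fell, 1 S phase gene fell, and 1 gene of G2 and mitosis rose and 2 fell. By camera the mitochondrial list passed, lower, without DMSO a (adjusted p = 0.00243; with all 6 libraries 0.682 with an estimated correlation, of 0.288). Of 58 ribosomal protein genes RPL22 alone fell (0 adjusted over the list alone; camera adjusted p = 0.341), a call lost without any single library other than DMSO a. Without DMSO a 27 passed and the ribosomal list ranked low (camera adjusted p = 2.58e-07), and without DMSO c it ranked high (0.0463). Both use the preset correlation of 0.01, whereas that estimated for ribosomal proteins with all 6 libraries was 0.905 (adjusted p = 0.859), so these calls carry little weight. Among markers of other cell types, LAPTM5 and CSF1R fell of the 3 leukocyte markers that could be tested. Of 7 endothelial markers 2 rose and none fell (3 rose adjusted over the list alone; camera adjusted p = 0.341), and 1 or 0 passed without any single library other than DMSO a. The endothelial median was -0.07, and its mean (0.19) and camera direction were positive.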

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

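The removal of the trend on GC content and length was chosen after the results were seen; the other alternatives here were planned. No called gene changed sign in any alternative. The 1009 genes past the threshold became 1015 with RLE size factors, 932 with library totals, 1017 with the stricter filter, 1420 with DESeq2 and 1027 with limma-voom. The count was 1685 without a filter (898 genes higher with Azeliragon), 59 in the test against a 1.5-fold change (10 genes higher with Azeliragon, 49 genes lower with Azeliragon) and 1751 with the GC and length trend removed (852 higher, 899 lower), of which 990 were among the 1009. DESeq2 called 690 genes higher. The excess of falls, 56.2% of the 1009, turned round without a filter (46.7% lower) and without DMSO a (45.4% lower). Falls were the larger part in all the other settings. With a library left out the count ranged from 445 without Azeliragon a to 3916 without DMSO a, with 154 to 2137 higher and 270 to 1779 lower. The other values were 473 without DMSO b, 819 without DMSO c, 500 without Azeliragon b and 448 without Azeliragon c. The 43 members of the primary lists past the threshold became 13 in the test against a 1.5-fold change and ranged from 29 to 79 with a library left out, the highest without DMSO a. Camera called 15 of 30 lists with the preset correlation and 1 with an estimated correlation. For cholesterol synthesis and uptake the estimate, 0.00241, was below the preset 0.01, yet the camera adjusted p rose from 1.08e-55 to 0.00196. The loss of calls is therefore not a matter of correlation alone. With an estimated correlation the camera adjusted p was 0.0749 for epithelial markers, 0.124 for mesenchymal markers and 0.180 for RAGE and its ligands. It was 0.150 for NF-kB targets and 0.109 for lung metastasis genes. Fry called 18 lists, among them each of these, with adjusted p of 0.00384, 0.00839, 0.0338, 0.0154 and 0.00609 in that order. Fry also called lists that camera with the preset correlation did not. These were MAPK and AP-1 response (fry adjusted p = 0.0364), aryl hydrocarbon (0.00609), cell cycle inhibitors and apoptosis (0.0364) and endothelial markers (0.0498). It did not call fatty acid synthesis and desaturation (0.199). The ribosomal proteins turned from lower to higher without DMSO c (camera adjusted p = 0.0463), and over the libraries left out their adjusted p ranged from 2.58e-07 without DMSO a to 0.583, all at the preset correlation of 0.01 (adjusted p = 0.859 at the estimated 0.905). Leaving out a library reduces the samples per group, and the causes of the other shifts were not tested. Libraries with the same letter did not deviate together (correlations across genes of 0.03, 0.02 and -0.04). This gives no sign of pairing by letter but cannot exclude it, as the labels do not say what a letter marks. With the letter as a replicate block 908 genes passed, 833 of them among the 1009. Of 113 called genes named by the rule, 72 stayed past the threshold in every set of 5 libraries and 109 in DESeq2, limma-voom and each scaling. CDH1, with 0 reads in DMSO and 1 with Azeliragon, was near absent at this depth in both conditions and could not be compared.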

Other observations

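The gene families in this part were chosen after the results were seen, as were the tests on library DMSO a and the removal of the trend on GC content and length; the other tests were planned. Because the 14 families were picked from these values, their members are given as counts without a test of the family. Of 9 genes of HLA class II antigen presentation tested, with the invariant chain CD74 and the regulator CIITA, 8 fell and none rose. HLA-DRA fell by 1.09, HLA-DPA1 by 0.91, CD74 by 0.86 and CIITA by 0.59 on the log2 scale, although members can share reads. Of 21 collagen genes 8 fell and 2 rose, COL8A1 and COL12A1. The carbonic anhydrases CA9 and CA12 fell among 7 tested, by 1.76 and 0.96. Of 8 inhibitor of DNA binding and BMP genes 4 fell, ID1, ID3, BMP1 and BMP4. In the other families, 7 of 12 S100, 3 of 5 HLA class I, 2 of 12 keratin, 2 of 3 NR4A, 1 of 3 early growth response and 1 of 10 laminin genes fell and none rose, while 2 rose and 4 fell of 23 interleukin and chemokine genes, 1 rose and 3 fell of 16 semaphorin genes, 1 rose and 3 fell of 10 ADAMTS genes, and 1 rose and 2 fell of 7 WNT genes.

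Among the 10 splits of the 6 libraries into 3 and 3, the real one gave 1009 genes and the highest other gave 1. Only 1 split gave as many as the real one, the real one itself, and 10 splits are too few for a share under 0.05.

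Library DMSO a differed from the other DMSO libraries. The median absolute log2 difference over 11712 genes was 0.15 from DMSO b and 0.20 from DMSO c, against 0.11 between DMSO b and c and at most 0.09 between Azeliragon libraries. Part of this followed transcript length. The deviation of each library from the mean of all 6 libraries was correlated with log2 length across genes. The correlation was 0.385 in DMSO a, -0.237 in DMSO b and -0.436 in DMSO c, and 0.192, 0.0106 and 0.256 in Azeliragon a, b and c. These values hold the treatment difference as well as the spread within DMSO, and genes are not independent replicates. With each library's GC and length trend removed the larger difference of DMSO a was still 0.139, above that between DMSO b and c, which argues against this trend as the whole cause. Without DMSO a 3916 genes passed before this removal and 3893 after it, with 2779 in both. Over 104 genes changed at least 2-fold without DMSO a, DMSO a lay a median 0.242 of the way to the Azeliragon mean on the log2 scale (bootstrap 95% interval 0.186 to 0.309), and over 3622 genes called without it 0.715 of the way. A mislabelled Azeliragon library would lie near 1. The bootstrap, here and below, resampled genes of 1 library, so its intervals measure the spread over genes and not between libraries. Over the 104 genes the median of 0.242 and its upper bound of 0.309 lie far from 1, which argues against mislabelling. The 0.715 of the 3622 genes lies nearer to 1. Library measures go the other way, as DMSO a was nearer to the Azeliragon libraries than to DMSO b and c in mitochondrial share of counts (5.03% against 4.88% to 4.96% and 5.54% to 5.71%), in the share of the 10 most abundant genes (6.79% against 6.59% to 6.73% and 7.30% to 7.32%) and in genes detected (23223 against 22450 to 22965 and 21993 to 22115). What sets these measures apart was not tested. The interval of 0.186 to 0.309 reaches across the bound of 0.25 first set against mislabelled or mixed RNA together, and the requirement that it clear the bound was added after the value was known. RNA mixed in from an Azeliragon library would move every gene by the same share of the way in CPM. Among the 104 genes the median share was 0.637 for genes higher and 0.241 for genes lower, a difference of 0.396 (bootstrap 95% interval 0.0665 to 0.596). The difference was 0.155 over the 3622 genes (0.102 to 0.206), and with the trend removed it was 0.499 (0.221 to 0.744) and 0.236 (0.183 to 0.287). As medians over genes of 1 library, these values argue against mixed-in RNA as the whole cause, without a measure of the spread between libraries. A smaller share of it beside another cause, and a difference between cultures, were not tested and stay open.

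The rise of cholesterol genes is the group change that held best. After removal of the GC and length trend 23 members rose, and the largest adjusted camera p with any library left out was 3.45e-47, so neither this trend nor a single library accounts for it. A hypothesis is that Azeliragon, or a difference in culture that goes with it, may lower the sterol sensed by the cells, since sterol synthesis genes rose while ABCA1 and NR1H3, on the export side, fell. The export side is weaker support, as the NR1H3 call was lost without DMSO b, Azeliragon a or Azeliragon c and the export list missed the threshold with an estimated correlation (adjusted p = 0.0749). Sterol levels were not measured, and sterol assays with and without added cholesterol would test the hypothesis. An action apart from RAGE stays open because no other RAGE inhibitor was compared.

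The lists of epithelial and mesenchymal markers both ranked low by camera with the preset correlation, but not with an estimated one (adjusted p = 0.0749 and 0.124). Fry called both lists lower (fry adjusted p = 0.00384 and 0.00839). The epithelial estimate, 0.0102, was near the preset 0.01, so a higher correlation does not account for that loss. The mesenchymal estimate was 0.0625. Members past the threshold were mostly lower, 9 of 31 and 11 of 34, while 21 of each list did not pass and 16 of the 34 mesenchymal markers were higher by any amount (median log2 fold change -0.04). After removal of the GC and length trend 22 members of the lists fell; the epithelial median log2 fold change went from -0.17 to -0.11 (median SE 0.12 to 0.10) and the mesenchymal one from -0.04 to -0.09 (0.09 to 0.06). The largest adjusted camera p with any library left out was 0.000107. These values argue against this trend and a single library as the whole cause of the ranking at the preset correlation. The cell cultures differ in treatment alone as labelled, so an unrecorded difference in density or harvest remains possible and was not tested.

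For SNAI1, the upper exact 95% bound of the Azeliragon share of reads was 23.1%, below the 49.3% held without a change, and the largest adjusted p with any library left out was 0.0179 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).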
